A study of Homo sapiens with 21 samples.

How the data were processed

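RNA of 13 Burkitt lymphomas taken as tissue and of 8 cell lines was measured on Affymetrix Gene 1.0 ST arrays, 1 array per sample. Per the labels' protocols, total RNA was purified on filter columns and labelled with biotin after oligo(dT)-primed cDNA synthesis and in vitro transcription with T7 polymerase. The submitters' processing notes name Affymetrix Expression Console and RMA, without versions; the genome build, the annotation release and any filter are not given in the sources used here. The deposited values are log2 expression values, 1 per transcript cluster and array, per the submitters' processing notes and the range of the values. RMA subtracts background, quantile-normalizes arrays and then summarizes probes, so arrays put through it together have equal distributions before the probes are summarized. The 2 groups here differed in median and quartiles, and the sources used here do not say whether RMA was run on all arrays at once or on each group. The scale difference and the group therefore cannot be told apart from the labels. No value column belonged to no sample (0 such columns).

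The table held 33297 transcript clusters. In the platform annotation 19460 had 1 gene symbol, 1754 had several and 12083 were unnamed. Entrez identifiers of 19429 clusters were found in the RefSeq gene table, and 0 symbols changed through them. Only clusters with 1 symbol were used; 45 clusters of Y-linked genes and of XIST and TSIX were left out of every table. For the 767 genes with several clusters the one with the highest mean over all 21 samples was kept, which gave 18374 genes. Coordinates are not printed, since no build is stated for the array annotation. Transcripts of gene families with shared sequence, such as HLA and globin genes, can hybridize to probes of their relatives. Pairs of arrays were compared over all clusters: Pearson's r was 0.946 to 0.988 within the tissue lymphomas, 0.958 to 0.981 within the cell lines and 0.887 to 0.961 between groups, across genes, which are not independent replicates, and 0 pairs were identical.

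Genes at log2 6 or more in at least 8 samples were tested, 15320 in all, with limma 3.58.1 (lmFit and eBayes, defaults) in R 4.3.3 on the deposited values, tissue lymphomas minus cell lines, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels give no batch or other covariate. Genes with an absolute log2 difference of 1 or more were counted as 2-fold. The 31 gene lists, of 457 names in all (417 with a gene here, a gene in 2 lists counted in each), were tested with limma's camera with a preset correlation of 0.01 where at least 5 members were tested, adjusted over the lists. The list score of a sample is the mean log2 value of the tested members. The spread of a score was compared between groups by the mean absolute deviation from the group median, with an exact permutation test over all 203490 splits. For 10 relations of scores across the tissue lymphomas, genes in both lists were left out of both scores, and Pearson's r and Spearman's rho were tested with 100000 permutations, 2-sided, with Benjamini-Hochberg adjustment over the relations; the smallest p these can give is 1e-05. For relations with 1 tissue lymphoma left out, 10000 permutations were used, whose smallest possible p is 9.999e-05. Scores and tests were computed in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.

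Groups, tests, lists, named genes and the first set of alternatives were chosen before the data were examined. The genes named in the text are the 12 with the largest positive and the 12 with the largest negative difference among those past the threshold, the 4 tested members of each list with the largest absolute difference whether or not they passed, and every tested member of the list of genes recurrently mutated in Burkitt lymphoma and of the germinal centre list. These rules gave 159 genes, of which the text names a part. The alternatives were no filter on low values, a filter at log2 7, the mean of a gene's clusters, median centring, centring on 18 housekeeping genes, quantile normalization, trended and robust variance, array weights, an exact Wilcoxon test, an adjusted p under 0.01, a log2 difference of 2 or more, camera with an estimated correlation, fry, the median in place of the mean for scores, and leaving out each sample in turn. Ranges of the adjusted p of a list are over the camera alternatives, since fry tests against no change and not against other genes. Added after the data were seen were the genes called alike in the deposited values and under all 3 scalings, the fit without the 6 tissue arrays of narrowest interquartile range, quantile normalization with an estimated correlation, quantile normalization for spread and relations, and relations on residuals after the array's interquartile range.

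On simulated data with the spread of the real genes (15320 genes, 13 against 8 samples), limma recovered 52.9% of 68 genes changed by 0.5 on the log2 scale, 93.9% of 66 changed by 1 and 100% of 66 changed by 2, and 6.29% of its calls were false. The simulated genes varied independently, few were changed and no shift of scale between groups was added. The 6.29% therefore does not give the share of false calls in the real data. The number of arrays, 13 and 8, limits the precision of each comparison.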

Results

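Gene expression was measured on 21 Affymetrix Gene 1.0 ST arrays, 1 for each sample. Of these, 13 held RNA of Burkitt lymphomas taken as tissue, whose labels give lymph as the tissue, and 8 held RNA of cell lines grown from Burkitt lymphoma: BL41, CA46, EB2, EB3, Jijoye, Namalwa, Raji and Ramos. Burkitt lymphoma is a fast-growing B-cell tumour of germinal centre origin in which MYC is activated. The series as a whole concerns the mutations of this lymphoma; the labels give the arrays no further factor, so the design implies the comparison of tissue lymphomas with cell lines and, within the tissue lymphomas, the relations between groups of genes. The labels do not say that the tissue samples came from separate donors, so p-values measure the spread between these samples. Array data carry no read depth, and the number of arrays limits the precision.

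The deposited log2 values of the 2 groups did not share a scale. The median of an array was 7.22 ± 0.053 in the tissue lymphomas (SD, n = 13) and 6.36 ± 0.040 in the cell lines (SD, n = 8), and the ranges of the 2 groups, 7.16 to 7.32 and 6.29 to 6.40, did not overlap. The lower quartile differed more, at 5.98 against 5.003, than the upper quartile, at 8.59 against 8.19. The median difference of all 15320 genes tested, tissue lymphomas minus cell lines, was 0.56 in the deposited values. With the filter on low values applied again after each scaling, the median was -0.051 after quantile normalization (14631 genes), -0.21 with each array centred on its median (14634 genes) and 0.69 with each array centred on 18 housekeeping genes (15216 genes). Differences below are in the deposited values, most with the value after quantile normalization beside them. A gene is called higher or lower only where it passed the threshold in the same direction in the deposited values and under all 3 scalings. Olfactory receptor genes, which neither kind of sample is known to need, had a median difference of 0.995 in the deposited values. Median centring moved differences by only -0.74, so this rule does not set a gene near 0.995 apart from background.

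**Figure D1:**
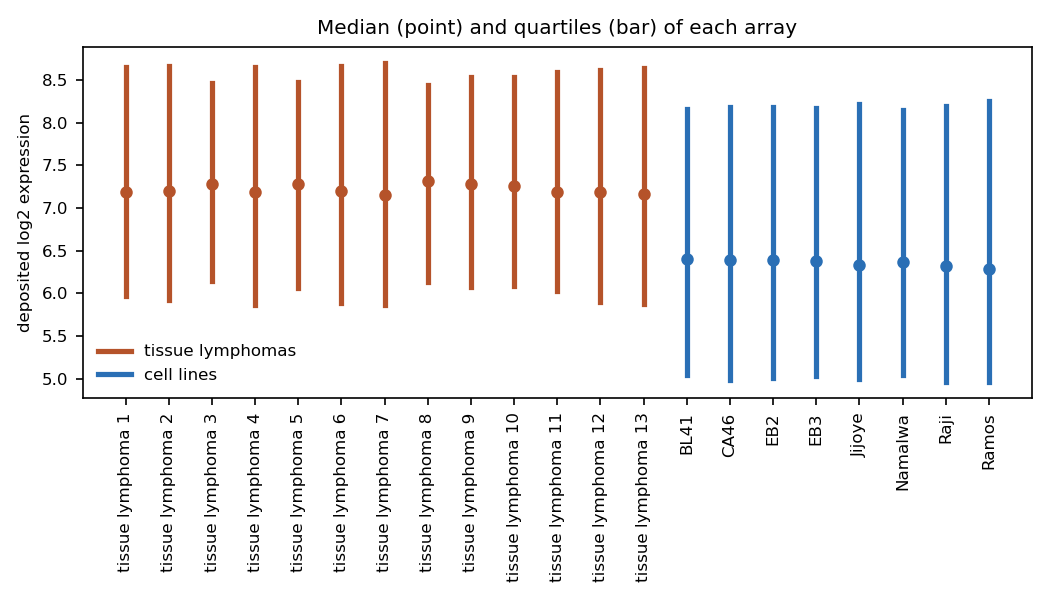
Deposited log2 expression of each array over all transcript clusters, with the median as a point and the lower to upper quartile as a bar, for the 13 tissue lymphomas and the 8 cell lines. Medians lay between 7.16 and 7.32 in the tissue lymphomas and between 6.29 and 6.40 in the cell lines.

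Genes of macrophages and of connective tissue were among the largest differences between tissue lymphomas and cell lines. LYZ, the lysozyme of monocytes and macrophages, was higher in the tissue lymphomas by 6.81 ± 0.43 on the log2 scale (SE; 6.18 after quantile normalization), at 11.56 ± 1.27 (SD, n = 13) against 4.75 ± 0.30 (SD, n = 8). FN1, which encodes fibronectin, was higher by 6.27 ± 0.25 (SE; 5.64 after quantile normalization). Genes of sterol synthesis were lower: MSMO1, a sterol C4-methyl oxidase, was at 8.08 ± 0.68 (SD, n = 13) against 9.99 ± 0.29 (SD, n = 8), a difference of -1.91 ± 0.24 (SE; -2.18 after quantile normalization). All 13 tissue lymphomas lay above every cell line for LYZ and FN1 and below every cell line for MSMO1. The adjusted p of limma's moderated test was 7.73e-12 for LYZ, 1.08e-14 for FN1 and 2.32e-07 for MSMO1.

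The 12 genes with the largest positive differences were LYZ, FN1, SPARC, GPNMB, LUM, CXCL9, PLA2G7, POSTN, CTSL, A2M, THBS1 and MGP, all higher in the sense above, with differences from 6.81 for LYZ to 4.81 for MGP. In the cell lines 8 of these 12, LYZ and FN1 among them, had a mean under 5.06, the mean of 341 olfactory receptor genes on the same arrays, as did 18 of the 62 named genes that were higher. Such genes read near background there, so the size of their differences and their order depend on the background of each probe set. SPARC, LUM, POSTN, THBS1 and MGP encode proteins of the extracellular matrix, and GPNMB, PLA2G7 and CTSL are expressed by macrophages. The 12 with the largest negative differences were MSMO1, MIR142, DHCR7, ALDOC, NDUFB3, SC5D, MLLT3, SNORD116-21, HMGCS1, SCD, ASF1A and RAB3A, all lower, with differences from -1.91 for MSMO1 to -1.47 for RAB3A. MSMO1, DHCR7, SC5D and HMGCS1 encode enzymes of cholesterol synthesis, SCD the stearoyl-CoA desaturase, ALDOC an aldolase of glycolysis and NDUFB3 a subunit of respiratory complex I. Of these 12, SNORD116-21 had the largest SD among the tissue lymphomas, 1.42 (n = 13), and MIR142 lay below every cell line in 7 of the 13 tissue lymphomas. Both are genes of small RNAs, and cDNA synthesis was oligo(dT)-primed, so their clusters need not measure the mature small RNAs. SNORD116-21 also belongs to a family of copies with shared sequence.

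By limma at an adjusted p under 0.05, 9772 of the 15320 genes tested read higher and 1200 lower in the tissue lymphomas, so 89.1% of the calls were higher. The split depended on the scaling. It was 2854 higher and 3998 lower after quantile normalization (41.7% higher), 2355 and 6478 with arrays centred on their median (26.7%), and 10736 and 859 with arrays centred on the housekeeping genes (92.6%). Of the 9772 genes that read higher, 2830 were also called higher after quantile normalization and 1283 were called lower; of the 1200 that read lower, 1183 were also called lower and 0 were called higher. In the deposited values and under all 3 scalings, 1643 genes were higher and 859 lower, of 14512 genes that could be tested in each. Housekeeping centring alone gave the same 859, so the other 2 scalings removed no lower call. A lower call under every scaling is thus that of housekeeping centring, which moved named differences by only 0.14. Since that centring kept the shift (median of all genes 0.69), the balance of 1643 and 859 still depends on the scalings chosen. A difference of 2-fold or more was found for 2995 higher and 74 lower genes in the deposited values, against 699 and 292 after quantile normalization, 644 and 1515 with median centring and 4133 and 45 with housekeeping centring; 565 and 45 genes held in all 4.

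Markers of macrophages and monocytes were higher as a group. In the deposited values 19 of 19 tested members passed the threshold upward, and 16 of them were higher under every scaling. CD68, a lysosomal protein of macrophages, was at 11.85 ± 0.49 (SD, n = 13) against 7.36 ± 0.36 (SD, n = 8), a difference of 4.49 ± 0.19 (SE; 4.16 after quantile normalization). The complement genes C1QB and C1QC were higher by 4.46 ± 0.24 and 4.33 ± 0.24 (SE; 3.86 and 3.75 after quantile normalization). The median difference of the list was 3.25, or 2.47 after quantile normalization. Its adjusted p by limma's camera, which sets a list against all other genes, was 7.13e-07. Over the camera alternatives it ran from 2.44e-18 to an adjusted p = 0.255 with an estimated correlation.

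Genes of connective tissue and of vessels were higher as well. All 21 tested genes of fibroblasts and matrix passed upward and 20 were higher under every scaling, with a median difference of 3.06 (2.47 after quantile normalization). SPARC, a matrix glycoprotein, was higher by 5.97 ± 0.15, LUM, which encodes lumican, by 5.87 ± 0.39 and POSTN, which encodes periostin, by 5.27 ± 0.30 (SE; 5.37, 5.51 and 4.79 after quantile normalization). For endothelium, 15 of 15 passed upward and 14 were higher under every scaling, among them CD34, at 9.30 ± 0.44 (SD, n = 13) against 5.36 ± 0.16 (SD, n = 8), CDH5, which encodes VE-cadherin, higher by 2.95 ± 0.15, and VWF, which encodes von Willebrand factor, higher by 2.93 ± 0.19 (SE; 2.22 and 2.18 after quantile normalization). For smooth muscle and pericytes, 8 of 8 passed upward and 7 were higher under every scaling, among them RGS5, by 3.001 ± 0.23, and MYL9, by 2.95 ± 0.17 (SE; 2.20 and 2.43 after quantile normalization). The camera adjusted p was 2.56e-07 for fibroblasts and matrix, 8.09e-06 for endothelium and 0.00563 for smooth muscle and pericytes. With an estimated correlation the adjusted p was 0.418, 0.415 and 0.418, the highest over the camera alternatives, whose lowest values were 7.54e-21, 1.31e-12 and 1.86e-06.

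T-cell and cytotoxic genes were also higher. All 14 tested T-cell genes passed upward and 11 were higher under every scaling. CD4 was higher by 2.63 ± 0.20, CD3E, a chain of the T-cell receptor complex, by 2.502 ± 0.33 and CD8A by 2.25 ± 0.27 (SE; 1.86, 1.87 and 1.61 after quantile normalization). CD3D was higher by 2.38 ± 0.33 (SE; 1.67 after quantile normalization), although only 7 of the 13 tissue lymphomas lay above every cell line, since Jijoye read 8.13. Of the NK and cytotoxic cell genes 9 of 9 passed upward and 8 were higher under every scaling. The list has 12 names, of which KLRB1, KLRD1 and KLRF1 did not pass the filter on low values. The 9 tested genes are not specific to NK cells. The granzyme genes GZMK and GZMA were higher by 4.57 ± 0.38 and 3.26 ± 0.25 (SE; 3.98 and 2.496 after quantile normalization) and lay above every cell line in all 13 tissue lymphomas. The camera adjusted p was 0.0135 for T cells and 0.00850 for NK and cytotoxic cells, and with an estimated correlation each had an adjusted p = 0.418. Over the camera alternatives the lowest values were 1.11e-07 and 4.43e-07.

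Chemokine genes were higher in all 11 tested members under every scaling. CXCL9, an interferon-gamma-induced attractant of T cells, was at 10.37 ± 1.29 (SD, n = 13) against 4.83 ± 1.05 (SD, n = 8). CCL18, CCL2 and CXCL12 were higher by 4.69 ± 0.54, 4.36 ± 0.23 and 3.51 ± 0.22 (SE; 4.11, 3.73 and 2.79 after quantile normalization). The list's camera adjusted p was 0.0129, and over the camera alternatives it ran from 2.42e-08 to an adjusted p = 0.418 with an estimated correlation. Of the 10 tested immune checkpoint genes, 8 passed upward and 6 were higher under every scaling, among them IDO1, the tryptophan-degrading dioxygenase, by 2.81 ± 0.29, HAVCR2, which encodes TIM-3, by 2.72 ± 0.22 and TIGIT by 2.07 ± 0.17 (SE; 1.997, 1.89 and 1.17 after quantile normalization). As a list they did not pass in the deposited values (camera adjusted p = 0.174), but they passed upward after quantile normalization (adjusted p = 0.00171), a call lost there with an estimated correlation (adjusted p = 0.207).

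The remaining markers of other cell types differed by group. Of 8 neutrophil genes tested, 8 passed upward and 5 were higher under every scaling, including MMP9 by 3.84 ± 0.51 and S100A9 by 2.61 ± 0.17 (SE; 3.20 and 1.87 after quantile normalization); the camera adjusted p was 0.0153, against an adjusted p = 0.418 with an estimated correlation and 0.000142 at the lowest over the camera alternatives. Of 6 follicular dendritic cell genes, 5 passed upward and were higher under every scaling, among them CLU by 3.28 ± 0.33 and FDCSP by 2.72 ± 0.42 (SE; 2.52 and 1.85 after quantile normalization), and of 6 dendritic cell genes 5 passed upward and 3, CD1E, CLEC10A and XCR1, were higher under every scaling. Neither list passed camera in the deposited values, with adjusted p = 0.228 and 0.144, while the follicular dendritic cell list passed upward after quantile normalization (adjusted p = 0.00504) and not there with an estimated correlation (adjusted p = 0.163). CD1E, at 1.29 (0.33 after quantile normalization), was little above the 0.995 of olfactory receptor genes in the deposited values. Of 5 red cell and platelet genes, 5 passed upward but HBB, the beta-globin gene, was the only one higher under every scaling, by 3.26 ± 0.33 (SE; 2.55 after quantile normalization); ITGA2B read 0.99 in the deposited values and 0.0042 after quantile normalization. Of 8 epithelial genes, 8 passed upward and 2, KRT8 and KRT18, were higher under every scaling. KRT8, at 1.11 (0.23 after quantile normalization), was little above the 0.995 of olfactory receptor genes in the deposited values. The epithelial list's median difference was 0.96 in the deposited values and -0.0051 after quantile normalization. Its camera adjusted p was 0.0281, and over the camera alternatives it ran from 0.0164 to an adjusted p = 0.759 with an estimated correlation after quantile normalization. Of 9 plasma cell genes, 3 passed upward and TNFRSF17, which encodes BCMA, was higher under every scaling, by 1.67 ± 0.39 (SE; 1.12 after quantile normalization).

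**Figure D2:**
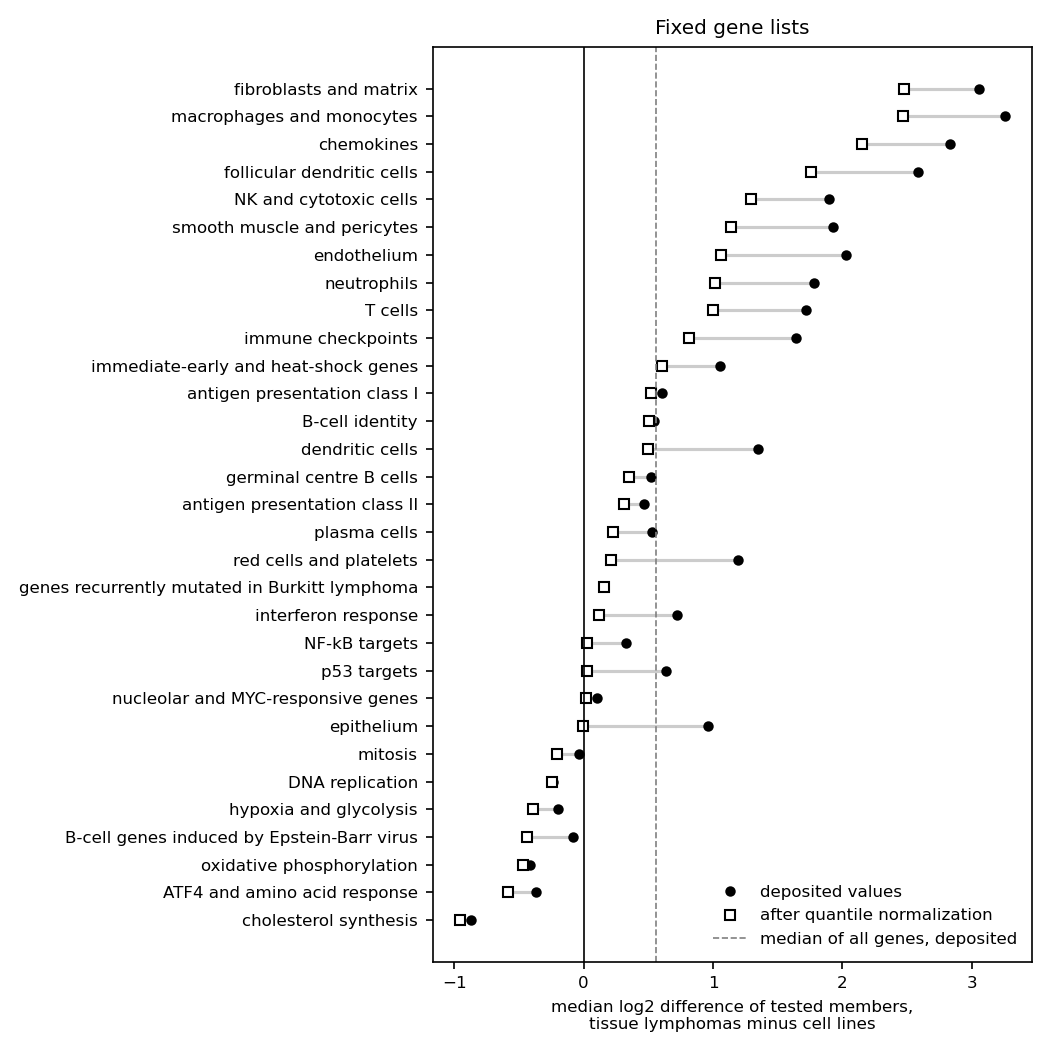
Median log2 difference, tissue lymphomas minus cell lines, of the tested members of each of the 31 gene lists, in the deposited values (filled points) and after quantile normalization (open squares). The solid line marks 0 and the dashed line the deposited median difference of all genes, 0.56. Macrophage and fibroblast lists lay at 3.25 and 3.06 in the deposited values and cholesterol synthesis at -0.87.

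Cholesterol synthesis genes were lower in the tissue lymphomas. Of 14 tested members, 11 passed downward in the deposited values and the same number were lower under every scaling, with 0 upward. DHCR7, which makes the last step of cholesterol synthesis, was at 8.25 ± 0.48 (SD, n = 13) against 10.06 ± 0.31 (SD, n = 8), a difference of -1.80 ± 0.18 (SE; -2.01 after quantile normalization), and all 13 tissue lymphomas lay below every cell line. SC5D differed by -1.61 ± 0.19 and HMGCS1, the cytosolic HMG-CoA synthase, by -1.49 ± 0.21 (SE; -1.95 and -1.76 after quantile normalization). The list's median difference was -0.87 (-0.96 after quantile normalization) and its camera adjusted p was 1.18e-12. Over the camera alternatives the adjusted p ran from 3.41e-17 to 0.147 with an estimated correlation. Camera does not match a list to genes of its level. Genes at a mean log2 of 8 to 9 and 9 to 10 had median differences of 0.26 and 0.056, against 0.56 for all genes. A part of the list's place below all genes is therefore that of its level.

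Some genes of mitochondrial respiration and of the amino acid response were lower. By camera both lists lay below all other genes, with adjusted p = 5.06e-11 for oxidative phosphorylation and 3.74e-07 for the ATF4 list, but not with an estimated correlation (adjusted p = 0.198 for both, and up to 0.314 for the ATF4 list after quantile normalization). The lowest values over the camera alternatives were 2.15e-13 and 1.32e-08. Part of the place of both lists is that of their level, since genes at a mean log2 of 8 to 10 shifted less than all genes. Their median differences, -0.41 and -0.37, still lay below the 0.26 of genes at 8 to 9 and the 0.056 at 9 to 10. Of 19 tested genes of oxidative phosphorylation, 13 passed downward and 2 upward in the deposited values, and 10 were lower under every scaling. NDUFB3 differed by -1.63 ± 0.20, COX5B, a subunit of cytochrome c oxidase, by -0.99 ± 0.14 and NDUFB5 by -0.98 ± 0.22 (SE; -2.15, -0.95 and -1.05 after quantile normalization). Of 16 genes of the ATF4 and amino acid response, 7 passed downward and 5 were lower under every scaling. Among them were the amino acid transporter genes SLC7A5, with a difference of -1.23 ± 0.19, and SLC7A11, with -1.15 ± 0.38, and SESN2, with -0.87 ± 0.21 (SE; -1.21, -1.78 and -1.41 after quantile normalization). Among the tissue lymphomas the oxidative phosphorylation score followed their first principal component after quantile normalization (r = 0.870), as did the interquartile range of the deposited array (r = 0.924), so within this group the score is not set apart from array quality. The interquartile range was 2.31 to 2.84 in the tissue lymphomas and 3.11 to 3.28 in the cell lines. The difference of this score between the groups is therefore not set apart from the array range either.

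The mitosis, nucleolar and hypoxia lists held members that passed in both directions, the DNA replication list only downward, and the 4 list calls ended after quantile normalization. Of 20 mitosis genes, 5 passed downward and were lower under every scaling, among them CDC20 with a difference of -1.07 ± 0.16 and AURKA with -0.74 ± 0.15 (SE; -1.04 and -0.91 after quantile normalization), and 2 passed upward in the deposited values. MKI67 read 10.64 ± 0.36 (SD, n = 13) against 9.95 ± 0.15 (SD, n = 8), a difference of 0.69 in the deposited values, 0.71 after quantile normalization and -0.048 with median centring. Of 18 DNA replication genes, 5 passed downward and 3 were lower under every scaling, among them CDC6 with a difference of -1.12 ± 0.18 and GINS2 with -1.05 ± 0.23 (SE; -1.35 and -1.01 after quantile normalization). Of 18 nucleolar and MYC-responsive genes, 3 passed upward and 3 downward. SRM, which encodes spermidine synthase, was lower under every scaling, with a difference of -0.74 ± 0.15 (SE; -0.70 after quantile normalization). Of 16 hypoxia and glycolysis genes, 3 passed upward and 5 downward. NDRG1 and EGLN3 were higher under every scaling, by 2.38 ± 0.25 and 1.76 ± 0.12, and PGK1, the glycolytic phosphoglycerate kinase, was lower, with a difference of -0.91 ± 0.15 (SE; 1.80, 0.996 and -0.85 after quantile normalization). The 3 lists whose counts differed when adjusted over the list alone were nucleolar genes, with 2 upward and 1 downward, mitosis, with 1 and 5, and DNA replication, with 0 and 3; in the other 28 lists the counts adjusted over the list alone were equal to those over all genes tested.

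In the deposited values these 4 lists lay below all other genes by camera, with adjusted p = 4.54e-06 for mitosis, 2.56e-07 for DNA replication, and 0.00172 for both the nucleolar and the hypoxia lists. Camera does not match a list to genes of its level, and the shift fell with level. Its median was 0.92 for genes at a mean log2 of 5 to 6, 0.056 at 9 to 10 and -0.085 at 10 to 12. Mean scores of these 4 lists lay between 9.13 and 10.07, so their place is partly that of their level. Median differences of mitosis and nucleolar genes, -0.039 and 0.10, were close to that level, and those of DNA replication and hypoxia, -0.24 and -0.20, lower. After quantile normalization the adjusted p was 0.282, 0.0650, 0.824 and 0.309 in the same order, and with an estimated correlation on the deposited values the adjusted p was 0.418, 0.415, 0.418 and 0.385. Over the camera alternatives the adjusted p ran from 2.04e-07 to 0.759 for mitosis, 5.75e-09 to 0.603 for DNA replication, 0.000181 to 0.932 for the nucleolar list and 0.000191 to 0.637 for the hypoxia list.

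B-cell identity genes read higher by about as much as the median of all genes in the deposited values (-0.017 relative to it), but lay 0.56 above it after quantile normalization, and none of the 13 B-cell identity genes was called in one direction under every scaling. Genes at a mean log2 of 10 to 12 had a median difference of -0.085 in the deposited values. The list, with mean scores of 10.69 in the tissue lymphomas and 10.15 in the cell lines, lay above genes of its level. CD22, a B-cell receptor inhibitor, read 11.30 ± 0.38 (SD, n = 13) against 10.32 ± 0.70 (SD, n = 8), and MS4A1, which encodes CD20, read 12.09 ± 0.64 against 11.29 ± 1.43 (adjusted p = 0.0907 by limma). Of 13 identity genes, 9 passed upward in the deposited values, and the median difference was 0.54 (0.50 after quantile normalization). Of 14 germinal centre genes, 4 passed upward and LMO2 was higher under every scaling, by 1.17 ± 0.12 (SE; 0.35 after quantile normalization). This was little above the 0.995 of olfactory receptor genes in the deposited values. BCL6, the germinal centre repressor, read 10.17 ± 0.81 against 10.08 ± 1.48, MME, which encodes CD10, 10.26 ± 0.69 against 10.06 ± 0.93, and MYBL1 9.41 ± 0.94 against 9.47 ± 0.85; none of these 3 passed the threshold. The camera adjusted p was 0.330 for B-cell identity and 0.228 for the germinal centre list. After quantile normalization B-cell identity passed upward (adjusted p = 0.00962), but not there with an estimated correlation (adjusted p = 0.336).

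Antigen presentation, interferon, NF-kB and p53 lists did not pass camera in the deposited values. Of 7 class I genes 4, of 9 class II genes 5, of 15 interferon response genes 9, of 14 NF-kB targets 5 and of 14 p53 targets 8 passed upward, with 0 downward in each. IFI27 in the interferon list, and TNFAIP2 and TNFRSF9 in the NF-kB list, were higher under every scaling, by 1.70 ± 0.30, 2.01 ± 0.17 and 1.69 ± 0.33 (SE; 0.97, 1.26 and 1.10 after quantile normalization). B2M, the invariant chain of class I molecules, read 11.89 ± 0.31 against 11.10 ± 0.36, and MDM2, a p53 target, 10.68 ± 0.38 against 9.92 ± 0.28 (SD, n = 13 and 8). The camera adjusted p was 0.875, 0.328, 0.678, 0.228 and 0.984 in the order of the lists. For class I, interferon and p53 the median relative to all genes was above 0, at 0.049, 0.16 and 0.083, while the test pointed down. After quantile normalization class I passed upward, with a median 0.57 above all genes (adjusted p = 0.0482), but not there with an estimated correlation (adjusted p = 0.477). Of 13 immediate-early and heat-shock genes, 11 passed upward and FOS, DUSP1 and JUN were higher under every scaling, by 2.42 ± 0.39, 2.08 ± 0.34 and 1.79 ± 0.29 (SE; 1.83, 1.71 and 1.06 after quantile normalization), while the list did not pass camera in the deposited values (adjusted p = 0.789). It passed upward after quantile normalization (adjusted p = 0.0350), but not there with an estimated correlation (adjusted p = 0.509).

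Genes recurrently mutated in Burkitt lymphoma were not called in one direction under every scaling in any of the 16 tested members. MYC read 10.79 ± 0.69 in the tissue lymphomas (SD, n = 13) and 10.99 ± 0.28 in the cell lines (SD, n = 8), a difference of -0.20 ± 0.24 (SE, adjusted p = 0.475 by limma). ID3, an inhibitor of the E2A protein encoded by TCF3, read 9.46 ± 0.88 against 10.05 ± 0.81, TCF3 10.49 ± 0.23 against 10.72 ± 0.27, and CCND3, which encodes cyclin D3, 10.32 ± 0.38 against 10.61 ± 0.70, none of which passed. ARID1A, a chromatin remodelling subunit, and FOXO1 passed upward in the deposited values, at 0.71 ± 0.11 and 0.63 ± 0.090 (SE), and after quantile normalization, at 0.71 and 0.55, but read -0.027 and -0.11 with median centring. In all, 6 members passed upward and 0 downward, and the camera adjusted p of the list was 0.0527.

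B-cell genes induced by Epstein-Barr virus varied widely between cell lines. Of 16 tested members 1 passed, upward, in the deposited values; this was HEY1, which read 0.90 in the deposited values and -0.034 after quantile normalization. After quantile normalization 4 members passed, all downward. The score of the list, the mean log2 value of its members, was 9.53 in Jijoye, 9.02 in Raji and 9.001 in EB2, and between 6.40 and 7.06 in the other 5 lines. In the tissue lymphomas it lay between 7.14 and 8.17. EBI3 read 8.14 ± 2.28 in the cell lines (SD, n = 8) against 6.99 ± 0.25 in the tissue lymphomas (SD, n = 13), and CCL22 8.53 ± 2.31 against 7.396 ± 0.35, with limma adjusted p = 0.0801 and 0.0921. After quantile normalization both passed downward, with differences of -1.80 and -1.65 (adjusted p = 0.00770 and 0.0159), as did FCER2, which encodes CD23, with -1.53 (adjusted p = 0.00139, against 0.0638 in the deposited values). In the deposited values each of these 3 passed when certain single samples were left out. The camera adjusted p of the list was 0.00194, in the downward direction; it was an adjusted p = 0.418 with an estimated correlation, and over the camera alternatives it ran from 3.28e-05 to 0.722.

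**Figure D3:**
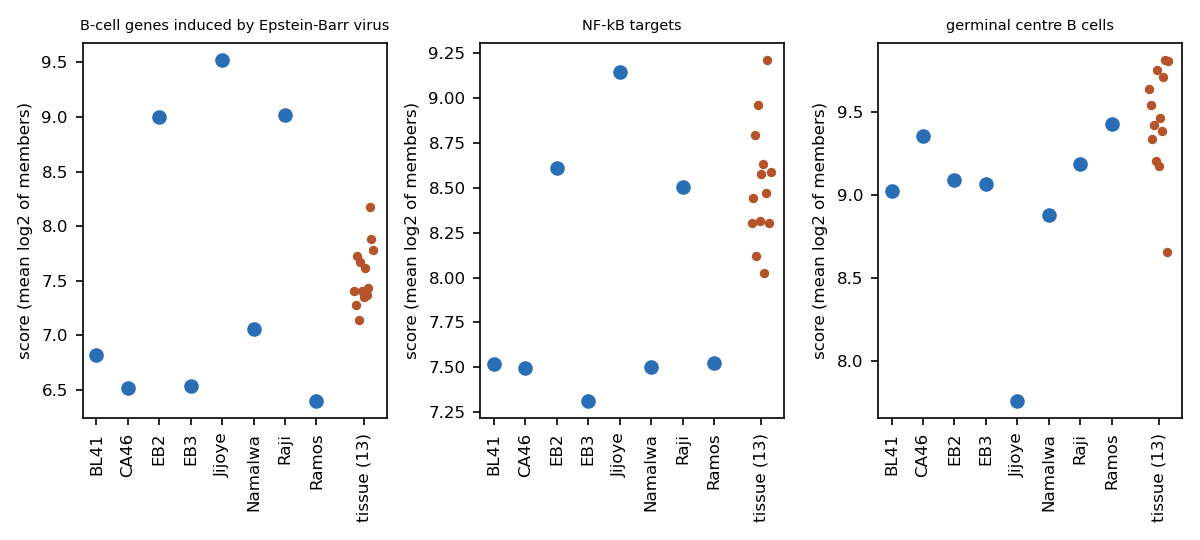
Scores, as the mean log2 value of the tested members, of 3 gene lists in each cell line and in the 13 tissue lymphomas, whose points are spread sideways only for legibility. The list of genes induced by Epstein-Barr virus lay at 9.001 to 9.53 in EB2, Raji and Jijoye and at 6.40 to 7.06 in the other lines, and the germinal centre score of Jijoye, 7.76, was the lowest of all samples.

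In all, 17 of the 31 lists passed camera in the deposited values, 9 upward and 8 downward, and 16 after quantile normalization, 13 upward and 3 downward. Of the 9 upward lists, 8 also passed upward after quantile normalization. No list held with an estimated correlation: 0 passed, and 4 had an unadjusted p under 0.05 in the deposited values and 8 after quantile normalization.

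The scores of several cell types had larger deviations among tissue lymphomas than among cell lines, but none passed the threshold. The mean absolute deviation of the NK and cytotoxic cell score was 0.46 in the tissue lymphomas and 0.087 in the cell lines (2-sided exact permutation test over 203490 splits, p = 0.00613, adjusted p = 0.0805). It was 0.36 and 0.14 for T cells (exact permutation p = 0.0238, adjusted p = 0.148), and 0.41 and 0.044 for fibroblasts and matrix (exact permutation p = 0.0361, adjusted p = 0.160). In the cell lines the means of these scores, 5.73, 5.78 and 5.56, were not far above the 5.06 of olfactory receptor genes. A small spread near background was to be foreseen there. The list of genes induced by Epstein-Barr virus went the other way, with 0.22 in the tissue lymphomas and 1.04 in the cell lines (exact permutation p = 0.00779, adjusted p = 0.0805). Of the 31 scores, 0 passed after Benjamini-Hochberg adjustment and 7 had an unadjusted p under 0.05.

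Across the 13 tissue lymphomas, T-cell genes varied together with genes of cytotoxic cells. The tested cytotoxic genes are not specific to NK cells, so the 2 scores need not come from different cells. The T-cell score ranged from 6.89 to 8.38 and the NK and cytotoxic score from 7.21 to 9.02, with Pearson's r = 0.873 (permutation p = 0.00014, adjusted p = 0.0014) and Spearman's rho = 0.912 (permutation p = 4e-05, adjusted p = 0.0004). Without the 2 samples farthest from the median T-cell score r was 0.791. T-cell and macrophage scores had r = 0.664 (permutation p = 0.0131, adjusted p = 0.0657) and rho = 0.692 (permutation p = 0.0106, adjusted p = 0.0531), and r = 0.516 without the 2 farthest samples, so this relation did not pass in the deposited values. It passed by r after quantile normalization (r = 0.713, adjusted p = 0.0301) and with housekeeping centring (r = 0.802, adjusted p = 0.00485), and not on residuals (adjusted p = 0.155). Fibroblast and endothelium scores had r = 0.502 (permutation p = 0.0797, adjusted p = 0.266) and rho = 0.379 (permutation p = 0.202, adjusted p = 0.505), and r = -0.089 without the 2 farthest samples, on which it rested. With housekeeping centring it passed (r = 0.742, permutation adjusted p = 0.0142), but r was 0.346 without the 2 farthest samples. That centring takes the same value of an array from both scores, which by itself can change r. The same limit holds for T-cell and macrophage scores with housekeeping centring.

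None of the other 7 relations of the 10 computed passed the threshold in the deposited values. Macrophage scores had r = 0.188 and rho = 0.626 with the interferon response (permutation p = 0.535 and 0.0249, adjusted p = 0.668 and 0.0828) and r = -0.247 and rho = -0.192 with B-cell identity (permutation p = 0.415 and 0.530, adjusted p = 0.593 and 0.659), and r was 0.072 and -0.362 without the 2 farthest samples. Without tissue lymphoma 11 the macrophage and interferon scores had r = 0.607 (adjusted p = 0.101) and rho = 0.923 (adjusted p = 0.0005), so the rank relation passed without that sample. The permutation p of this rho, 9.999e-05, was the smallest that 10000 permutations can give. T-cell scores had r = -0.259 and rho = -0.258 with mitosis (permutation p = 0.389 and 0.395, adjusted p = 0.593 and 0.565), and r = -0.215 without the 2 farthest. The 4 further relations, of macrophages with fibroblasts, T cells with class II genes, fibroblasts with B-cell identity and germinal centre genes with mitosis, had r from -0.356 to 0.306 (permutation p from 0.238 to 0.766, adjusted p from 0.593 to 0.766) and rho from -0.258 to 0.330 (permutation p from 0.271 to 0.807, adjusted p from 0.542 to 0.807). The interquartile range of the arrays varied among the tissue lymphomas from 2.31 to 2.84, and on residuals after this range was taken out the T-cell and cytotoxic scores had r = 0.842 and rho = 0.863 (permutation p = 0.00039, adjusted p = 0.0039).

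**Figure D4:**
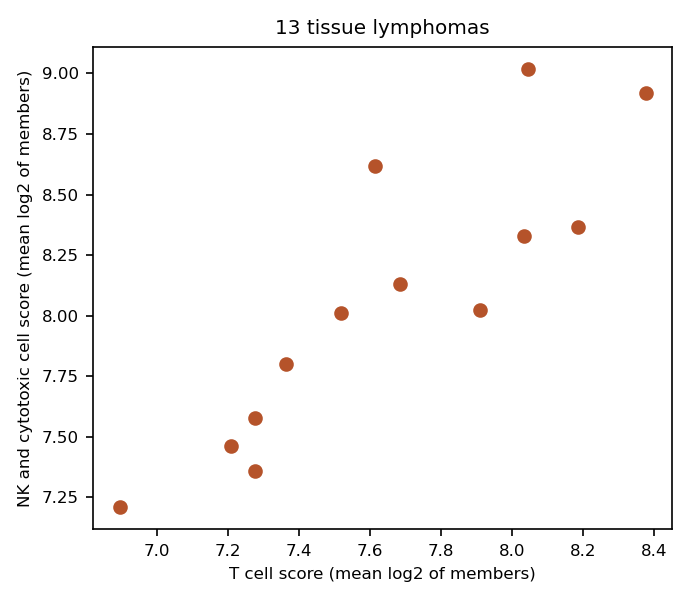
T-cell score (horizontal) and NK and cytotoxic cell score (vertical), each the mean deposited log2 value of its tested members, in the 13 tissue lymphomas. The scores rise together, with r = 0.873 and rho = 0.912.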

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

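The values tested here were the levels of 159 named genes and 31 list scores in the 8 cell lines; in 27 of these 190 the highest or lowest line stood apart from the nearest of the other 7 by more than Dixon's criterion allows. Chance alone flags about 1 in 20, or 9.5 of 190, and the genes are not independent. The tissue lymphomas, being more than 10, were not tested in this way. Jijoye stood apart in 10, EB2 in 7, Namalwa in 4, CA46 and Ramos in 2 each, and BL41 and Raji in 1 each. No explanation was tested for any single line.

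Jijoye was the highest line for CXCL9, at 7.42 against 4.38 to 4.55 in the others, CD3D, at 8.13 against 5.09 to 5.61, CXCL13, at 6.40 against 3.83 to 4.62, HBD, at 6.89 against 5.22 to 5.88, and TNFAIP2, at 6.55 against 5.74 to 5.89, and for the chemokine score, at 6.53 against 5.12 to 5.74. It was the lowest line for BCL6, the germinal centre repressor, at 6.60 against 10.02 to 11.46, for BLK, a B-cell kinase, at 6.77 against 8.46 to 9.52, for S1PR2, at 7.55 against 7.99 to 8.25, and for the germinal centre score, at 7.76 against 8.88 to 9.43.

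EB2 was the highest line for the interferon-induced genes RSAD2, at 5.81 against 4.33 to 4.77, IFI27, at 8.16 against 5.73 to 6.26, and XAF1, at 9.82 against 5.87 to 7.14, and for EGR1, at 10.93 against 7.68 to 8.81, LMO2, at 7.16 against 5.95 to 6.52, and FPR1, at 5.54 against 5.01 to 5.25. It was the lowest for CDC6, at 8.62 against 9.26 to 9.84. Namalwa was the lowest line for MS4A1, which encodes CD20, at 7.90 against 11.22 to 12.57, MIR142, at 7.02 against 8.30 to 9.44, and RHOA, at 11.76 against 12.22 to 12.55, and the highest for CDC20, at 11.49 against 10.69 to 11.06. Raji was the highest for SERPINA9, at 10.59 against 5.24 to 7.22. Ramos was the lowest for the p53 target DDB2, at 7.55 against 8.68 to 9.70, and for DUSP1, at 6.46 against 7.47 to 7.98. CA46 was the highest for HAVCR2, at 6.11 against 4.31 to 4.99, and the lowest for CLU, at 4.67 against 4.88 to 5.06. All of these CLU values lay under the olfactory receptor mean in the cell lines, so this is a rank among background values. BL41 was the lowest for RAB3A, at 7.91 against 9.12 to 9.75.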

How the results depend on the processing

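Genes called in the deposited values and under all 3 scalings, the fit without 6 arrays, quantile normalization with an estimated correlation, and quantile normalization for spread and relations, and residuals for relations were chosen after seeing the data. The scaling moved the split between higher and lower genes, and the estimated correlation took away every list call; what set the 2 groups on different scales was not stated. Signal over background limits the low genes. No paired analysis was possible because the labels give no number shared between tissue lymphomas and cell lines.

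Of all genes, 10972 differed in the deposited values (9772 higher, 1200 lower). There were 6852 after quantile normalization (2854 and 3998), 2355 higher and 6478 lower with median centring, and 2502 (1643 higher) in the deposited values and all 3 scalings. With the stricter filter, which tests fewer genes, 7148 differed and 6023 were higher. At an adjusted p under 0.01, 8890 were higher and 778 lower, and without the 6 narrowest tissue arrays 10350 and 654, or 11004 in all. Of 3069 genes at 2-fold or more, 1731 were left by the stricter filter (1660 higher), 991 by quantile normalization (699 and 292), 610 in the deposited values and all 3 scalings (565 and 45) and 469 at a log2 difference of 2 or more, with 469 higher and 0 lower by limma. Median centring gave 644 and 1515, housekeeping centring 4133 and 45, and the fit without 6 arrays 2413 and 36. Leaving out each sample in turn gave 10715 to 10972 genes (9593 to 9867 higher, 1082 to 1308 lower) and 2911 to 3163 at 2-fold or more (2847 to 3076 and 63 to 93).

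Of 17 lists, 0 were called with an estimated correlation, upward or downward, and 0 after quantile normalization with an estimated correlation; fry, which tests whether a list moves and not whether it moves more than other genes, called 26 (23 higher, 3 lower), and quantile normalization called 3 lower. Leaving out each sample in turn gave 17 to 19 lists (9 to 10 higher, 8 to 9 lower): the recurrently mutated list, short of the threshold with all samples, passed without tissue lymphoma 2, 3, 6, 7, 10 or 11, Jijoye or Namalwa, and red cells and platelets without tissue lymphoma 2, 4 or 6 or Jijoye. Of the single lists, 2 turned upward relative to all genes after quantile normalization, B-cell identity to 0.56 and class I to 0.57. With fry 12 pointed the other way, at median differences of 0.53 for plasma cells, 0.54 for B-cell identity, 0.52 for germinal centre B cells, 0.33 for NF-kB targets, -0.081 for genes induced by Epstein-Barr virus, 0.10 for nucleolar genes, 0.61 for class I, 0.47 for class II, 0.72 for interferon, -0.20 for hypoxia, 0.64 for p53 and 0.15 for recurrently mutated genes. The medians of the genes induced by Epstein-Barr virus and of hypoxia stayed below 0, and fry did not pass for these 2 (adjusted p = 0.781 and 0.218). Leaving out single samples reversed 0 list directions.

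The spread test called 0 scores under every alternative run, leaving out each sample in turn included. The relations past the threshold were 1 in the deposited values, 3 with housekeeping centring and 2 after quantile normalization, and 1 to 2 on leaving out each tissue lymphoma; without tissue lymphoma 11, T cells with macrophages reached r = 0.8004 (permutation adjusted p = 0.0090; over its alternatives 0.00485 to 0.260). The relation of T-cell with cytotoxic scores kept r between 0.736 and 0.918 over the alternatives run for relations, with permutation adjusted p from 0.0004 to 0.0437. Median centring and the stricter filter were not run for relations.

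Genes are counted as turned here only if they passed the threshold in the deposited values or in the alternative. Of 159 named genes, 1 turned after quantile normalization, HEY1 to -0.034, and 16 with median centring: MYBBP1A to -0.12, NCL to -0.43, MKI67 to -0.048, TAP2 to -0.048, TAP1 to -0.13, HLA-DMA to -0.21, ARID1A to -0.027, FOXO1 to -0.11, USP7 to -0.23, SMARCA4 to -0.25, FBXO11 to -0.31, DDX3X to -0.50, PIK3R1 to -0.35, GNAI2 to -0.67, S1PR2 to -0.57 and BCL7A to -0.28. Median centring moved every named difference by -0.74, so these 16 had read higher by less than that. A further 15 lost and 6 gained the threshold after quantile normalization, 21 and 14 with median centring. Of the comparisons that left out 1 sample, 0 reversed a named gene, 3282 left its call as it was, 46 brought it past the threshold and 11 took it away; among those gained, EBI3 (0.0801 adjusted) passed without BL41, CA46, EB3 or Ramos, CCL22 without BL41, CA46 or Ramos, and FCER2 without tissue lymphoma 12, EB3 or Ramos.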

Other observations

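The tests of the cholesterol synthesis pattern and the counts over other splits of the samples were chosen after their results were seen; the tests of the overall shift and of the tissue axis were chosen before.

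Among the 13 tissue lymphomas, scores of proliferation and respiration rose along the first principal component, while scores of connective tissue and several other cell types fell. The first principal component of the tissue lymphomas after quantile normalization, which held 28.9% of their variance, followed the score of oxidative phosphorylation (r = 0.870, rho = 0.896, permutation p = 9e-05 and 6e-05, adjusted p for r = 0.0006) and of mitosis (r = 0.830, rho = 0.868, permutation p = 0.00051 and 0.00022, adjusted p for r = 0.00255). It ran against the score of fibroblasts and matrix (r = -0.806, rho = -0.753, permutation p = 0.00133 and 0.00425, adjusted p for r = 0.00443) and hardly moved with B-cell identity (r = 0.089, rho = -0.115, permutation p = 0.775 and 0.709, adjusted p for r = 0.775). Without the 2 samples farthest from the median score r was 0.852 for oxidative phosphorylation, 0.734 for mitosis, -0.528 for fibroblasts and matrix and 0.019 for B-cell identity. It also followed cholesterol synthesis (r = 0.799, rho = 0.588, permutation p = 0.00172 and 0.0381, adjusted p for r = 0.00491, r = 0.707 without the 2 farthest). It ran against immediate-early and heat-shock genes (r = -0.739, rho = -0.621, permutation p = 0.00487 and 0.0274, adjusted p for r = 0.0108, r = -0.539 without the 2 farthest). Smooth muscle and pericytes (r = -0.721), endothelium (r = -0.685), dendritic cells (r = -0.612) and neutrophils (r = -0.597) ran against it too. The nucleolar list followed it (r = 0.681). For these lists the permutation adjusted p for r ran from 0.0108 to 0.0497. The component followed the interquartile range of the deposited array still more closely (r = 0.924), so these relations are not set apart from array quality. Of the family, 20 relations were computed, and the list members are among the genes that make up the component.

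Most genes read higher in the tissue lymphomas in the deposited values, with a median difference of 0.56. If transcripts of other cells in the tissue raised most genes, the olfactory receptor genes, which neither kind of sample is known to need, should not share the shift; 341 of 341 did, or 100% (exact binomial 95% interval 98.9% to 100%), which argues against that explanation for the shift as a whole. Their median difference was 0.995 (bootstrap 95% interval over genes 0.967 to 1.04), close to the 0.873 of other genes at the same level, and 91.2% of the 12083 unnamed clusters read higher too. This is consistent with the 2 groups having been put on different scales before deposit, as separate RMA runs may do. A higher background on the tissue arrays could do the same and was not tested apart from it. The mean of an array was 7.31 to 7.36 in the tissue lymphomas and 6.67 to 6.71 in the cell lines. These means were thus close within each group and apart between the groups. Within the tissue lymphomas the interquartile range of the arrays varied from 2.31 to 2.84. RMA makes arrays equal before it summarizes probes, so this range does not speak against 1 run per group.

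Cholesterol synthesis genes read lower in the tissue lymphomas, by a median of -0.87. After quantile normalization 13 of 14 tested members passed downward, which argues against a difference of scale as the whole cause. In the deposited values and under all 3 scalings 11 of 14 were lower. Median centring moved differences by -0.74 and housekeeping centring by 0.14, so these 2 scalings could hardly undo a lower call. Dilution by RNA of other cells should lower B-cell identity genes alike. The median of the cholesterol list lay below theirs by -1.46 after quantile normalization (bootstrap 95% interval over genes -2.26 to -1.12). This interval holds no spread between samples. B-cell identity genes themselves read higher by a median of 0.50, which dilution alone would not give. They differ for some other reason, which could hide dilution, so the comparison cannot decide on dilution and no conclusion is drawn from it. Within the tissue lymphomas the cholesterol score did follow the first component (r = 0.799), which ran against the mean score of other cell types (r = -0.801) and with the range of the array, so a part due to tissue content or array quality stays open. Without the 6 tissue arrays of narrowest range the median relative to all genes was -1.26, against -1.43 with them. A biological difference between growth in culture and in tissue stays open as well, untested, since the design confounds it with the group.

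The tissue lymphomas spread along 1 axis that follows the interquartile range of the array, with r = 0.950 (rho = 0.929, permutation p = 1e-05 for both, the smallest the permutations can give; r = 0.940 without the 2 farthest arrays) for the first component of the deposited values, 33.1% of their variance. Compression of all signals on some arrays should vanish after quantile normalization, but r with the deposited interquartile range was still 0.924 (rho = 0.868, permutation p = 3e-05 and 0.00026, r = 0.895 without the 2 farthest), which argues against it as the whole cause. The mean score of 10 lists of other cell types had r = -0.801 with the component (rho = -0.643, permutation p = 0.00116 and 0.0210), just past the bound of 0.8 set in advance, and r = -0.516 without the 2 samples farthest from its median, so the content of other cells stays open and rests on those samples. RNA quality could act in the same way and was not tested, since the labels give no measure of it.

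The real grouping gave more genes than every other split drawn, but not more lists than every other split. Of 100 splits of the 21 samples into 13 and 8, the real one included, 1 gave as many genes as the real 10972, and the highest other split gave 0; for differences of 2-fold or more, 1 gave as many as the real 3069, and the highest other gave 0. Splits that mix the groups carry the difference between them, scale included, in their spread, so the 0 does not measure how many of the genes differ for another reason than scale. Since the array medians of the 2 groups did not overlap, a count near 0 in mixed splits was to be foreseen. The comparison of gene counts therefore cannot decide on chance, and no conclusion is drawn from it. For the lists 6 of 100 splits gave 17 or more, and the highest other gave 22, so a count of lists by camera with a preset correlation of 0.01 is reached by splits that mix the groups. The median over the other splits was 9 lists.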
